A study of Mus musculus with 18 samples.

How the data were processed

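Bulk RNA sequencing covered 15 mouse libraries (iPax3, iPax7, Emb, Fet and Neo, 3 each) and droplet single-cell RNA sequencing covered adult satellite cells and iPax3 cells. Per the labels, bulk reads were processed with CASAVA 1.8, aligned to mm10 with HISAT2 2.0.2 and assigned to genes with Subread featureCounts 1.4.6, and the deposited values are read counts per gene. The annotation release, the strand setting and the handling of reads that map to several places were not stated. Single-cell data were processed by the authors with Cell Ranger 2.2.0, and the deposited matrices hold UMI counts for every listed barcode, with barcode and gene name files as the other deposited columns. Deposited cluster tables give a signal (mean UMI count per cell of a cluster, scaled), a log2 fold change and an adjusted p-value computed over cells; these p-values take cells as replicates, and no value from these tables is printed. The identity of the units was checked on the values.

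Of 47728 gene identifiers in the bulk counts, 47223 matched GENCODE M21 (GRCm38), which gave symbols and positions, and 505 did not. Total counts per library ranged from 516504 (Fet replicate 1) to 56275318 (iPax3 replicate 1), and 12850 to 22814 genes had a count. Counts of replicate pairs differed by more than counting error (chi-square per degree of freedom 8.0 to 510), so counting error alone understated the spread between libraries. Replicate numbers did not pair samples across groups (correlation of same-numbered residuals -0.331 to 0.0767).

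Genes were filtered with filterByExpr, leaving 17571, and scaled by TMM. A robust quasi-likelihood model with 1 mean per group was fitted in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) to all 15 libraries. The 10 pairs of groups and the contrast of PSC-derived with tissue-derived groups were tested with Benjamini-Hochberg adjustment over all tested genes at 0.05. An adjusted p of a gene comes from this test unless another model or setting is named beside it. Log2 CPM used a prior count of 2. Genes with 0 counts throughout a group are given as at least a fold, with a floor of 3 counts over the group. These bounds cover counting error only, not spread between libraries or genes a library missed. The comparisons, gene lists and naming rule were chosen before the data were examined. The naming rule took genes past the threshold, with all libraries of one group above all of the other (chance gives 10% for 3 against 3), a mean of at least 20 CPM in the higher group, and no predicted genes, pseudogenes, Y-linked genes, Xist or Tsix. It took the 10 largest fold changes each way, or 5 where a PSC-derived group met a single stage. It also named Pax3, Pax7, Myf5, Myod1 and Myog, and up to 4 members of a described list by smallest adjusted p.

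The 26 gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated per list and with fry. They held myogenic regulators, embryonic and oncofetal genes, a fetal myogenic programme, satellite cell markers, Notch, contractile, cell cycle, CDK inhibitor, extracellular matrix, Hox, imprinted, antigen presentation and interferon, glycolysis and hypoxia, oxidative metabolism, and cholesterol synthesis genes. They also held BMP, TGF-beta and Wnt targets, immediate early and dissociation, and pluripotency genes, and markers of neural, immune, erythroid, endothelial, fibroblast, tendon and cartilage, pericyte and epithelial cells. Lists were compiled from general knowledge and some share genes: the matrix and fibroblast lists share Dcn and Lum, satellite and Notch lists share 3 genes, and satellite and fetal programme lists share 3. Stage signatures were genes higher in one tissue stage than in each of the other two at a log2 fold change of 1 or more. Each iPax library was correlated with the mean of each stage, and sign-flip tests of the differences between stages were added after the data were seen. The model was tested on simulated counts, with a mean and a spread per gene estimated over all 15 libraries.

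Cells were barcodes with at least 10% of the 99th percentile of the 3000 largest barcodes, at least 500 UMIs and under 10% mitochondrial UMIs. This gave 579 adult and 2931 iPax3 cells, with medians of 2179 and 2312 genes. Scrublet, as run in scanpy, called 2 adult and 0 iPax3 cells doublets, and these were kept except in an alternative. UMIs were summed over cells, and ratios carry exact 95% intervals. A named gene needed 100 CPM in the higher sample, and the 10 largest ratios each way were taken. List medians, with members of at least 20 summed UMIs and a floor of 3 UMIs, were placed among 10000 random lists matched in 50 expression bins. Clusters came from scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, igraph 0.11.9). They were made on log-normalised counts that were not thinned to a common depth, with 2000 variable genes, 20 components, 15 neighbours and Leiden resolution 0.5. A cluster took a cell type's name with 3 or more markers at least 2-fold over all other cells and detected in 10% of its cells. After this left the largest adult clusters unnamed, a second rule, over the median of the other clusters, was tried and left them unnamed too. With 1 library per sample no test was made.

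The second iPax3 file was left out of the comparisons, since it pools 590 cells that share 577 barcodes with the adult sample and 3327 cells that include all 2931 barcodes of the first iPax3 sample. It adds no replicate and served as an alternative of greater depth. All 15 bulk libraries were kept in the model, including the library labelled iPax7 replicate 1. Alternatives were RLE and total-count scaling, DESeq2 1.42.0, other low-count filters, a fold threshold, a replicate block, a model of 2 groups alone, the 20 most abundant genes left out, each library left out in turn, and other cell, cluster and correlation settings. Added after the data were seen were models without the library labelled iPax7 replicate 1, alone or with Fet replicate 1, libraries thinned to the smallest total, the deeper iPax3 sample, the second cluster naming rule, and adult cells without the clusters named as other cell types.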

Results

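RNA was measured in mouse myogenic progenitors made from pluripotent stem cells (PSC) and in muscle progenitors sorted from tissue at 3 stages of development. The bulk RNA sequencing held 15 libraries in 5 groups of 3. The groups iPax3 and iPax7 were PSC-derived progenitors, named after the paired-box regulators Pax3 and Pax7, that had been sorted as Vcam1-positive, Flk1-negative cells of embryoid bodies and grown with doxycycline and bFGF. Counts of Pax3 and Pax7, in bulk and in single cells, were not split into transcripts of an inducing factor and of the cell's own gene. The groups Emb (E10.5) and Fet (E14.5) came from mice in which Cre driven from the Myf5 locus switches on YFP. The group Neo, labelled neonatal satellite cells, came from hindlimb muscle at postnatal day 3 of mice with a Pax7-ZsGreen reporter. Droplet single-cell RNA sequencing covered adult Pax7-ZsGreen cells of the tibialis anterior at 3 months and iPax3 cells. Libraries of engrafted and re-isolated cells, which the series design mentions, were not among the samples.

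Total read counts per library were 56275318, 41307537 and 38798892 for iPax3 replicates 1 to 3, and 27554142, 27768610 and 15852638 for iPax7. They were 11804719, 18266914 and 14228051 for Emb, 516504, 32017618 and 13487821 for Fet, and 16917199, 6923705 and 3557117 for Neo. Emb replicate 1 had 14552 genes at a normalised count (CPM, counts scaled to a common library total) of 1 or more, against 10182 and 10330 in the other two Emb libraries. The 20 most abundant genes took 6.90 to 8.90% of counts in the iPax libraries, 7.83 to 8.55% in Emb, 10.6 to 12.4% in Fet and 17.9 to 19.9% in Neo. Mitochondrial transcripts took at most 3.01% of counts in iPax and Emb libraries and 6.62 to 11% in Neo. Below, ± after a log2 fold change is an approximate standard error, the size of the change divided by the square root of the test's F statistic. It comes from fits with 3 libraries per group unless stated otherwise. After a CPM, ± is the SD over 3 libraries. Folds given as at least a value cover counting error only, not genes a library missed. The p-values measure the spread between these samples, which may be technical.

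Pax3 (ENSMUSG00000004872, GRCm38 chromosome 1, 78101267 to 78197134), a regulator of embryonic muscle progenitors, stood at 331 ± 32.1 CPM in iPax3, 2.30 ± 1.34 in iPax7, 95.6 ± 39.4 in Emb, 4.90 ± 2.76 in Fet and 1.45 ± 2.15 in Neo. Pax7 (ENSMUSG00000028736, chromosome 4, 139737062 to 139833528), its paralog in fetal and satellite cells, stood at 0.210 ± 0.0631 CPM in iPax3, 154 ± 178 in iPax7, 27.8 ± 6.57 in Emb, 43.8 ± 11.4 in Fet and 3.23 ± 2.42 in Neo. The libraries labelled Neo thus held little of their reporter's gene (0.495, 4.08 and 5.12 CPM, from 7, 25 and 17 counts), and endothelial markers averaged 6.81 to 7.59 log2 CPM in them, against 3.18 to 4.90 in Fet and at most 1.54 in Emb and iPax libraries. The determination factor Myf5 (ENSMUSG00000000435, chromosome 10, 107482908 to 107486134) was at 248 ± 67.8 CPM in iPax3, 57.4 ± 48.8 in iPax7 and 27.6 ± 6.90 in Emb. The differentiation factor Myog (ENSMUSG00000026459, chromosome 1, 134289989 to 134292548) ranged from 66.4 ± 33.5 CPM in iPax3 to 501 ± 351 in Emb. The library labelled iPax7 replicate 1 stood apart from its group. It held Pax7 at 0.989 CPM, against 111 and 349 in the other two iPax7 libraries, and Myog at 1.58 CPM against 563 and 517. It held the pluripotency factors Sox2, Pou5f1 and Nanog at 505, 550 and 511 CPM, where no other iPax library passed 8.41 CPM.

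**Figure D1:**
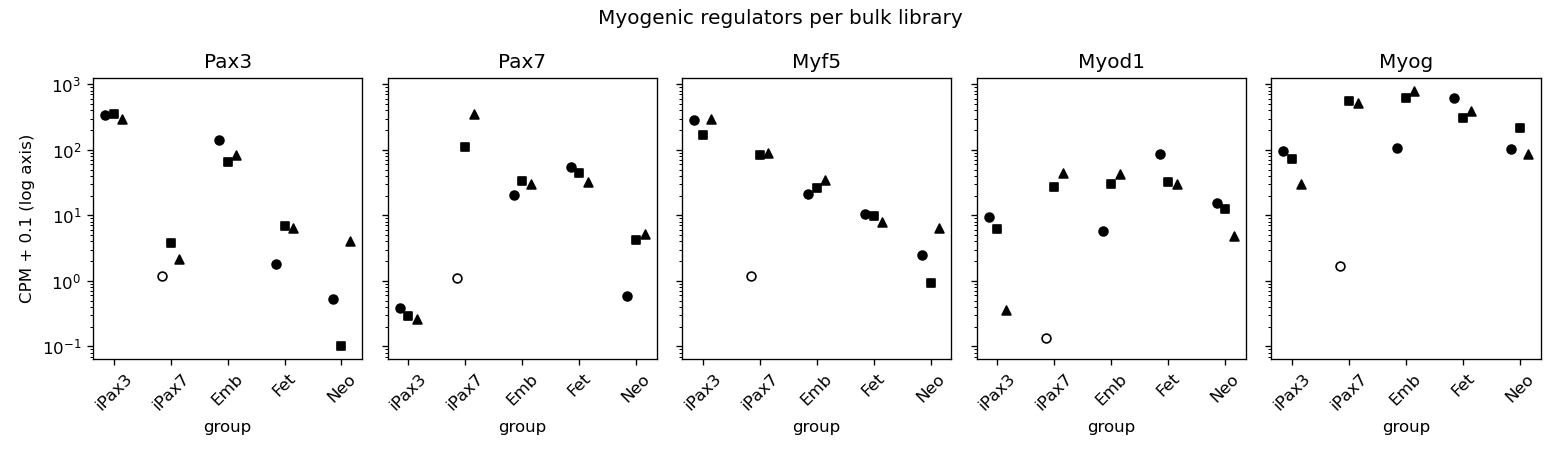
CPM of Pax3, Pax7, Myf5, Myod1 and Myog in each of the 15 bulk libraries, plotted as CPM + 0.1 on a log axis, with circles, squares and triangles for replicates 1, 2 and 3 and an open circle for the library labelled iPax7 replicate 1. Pax3 was highest in the iPax3 libraries, and the open circle lies at 0.989 CPM for Pax7 beside 111 and 349 in the other two iPax7 libraries.

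The contrast of both PSC-derived groups with the 3 tissue groups asked which genes separated cultured from tissue progenitors. The tumour suppressor Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) was higher in PSC-derived cells (89.7 against 0.123 CPM, log2 fold change 10.59 ± 0.79, adjusted p = 4.4e-07). So were the mesothelial antigen Msln (9.03 ± 0.65), the simple-epithelium keratin Krt8 (8.49 ± 0.43), the desmosomal Pkp2 (8.33 ± 0.88), the CDK inhibitor Cdkn2b (7.35 ± 1.02), Tmprss11f, AU018091, Ptprn, Ano3 and Nme4. The matrix proteoglycan Lum (ENSMUSG00000036446, chromosome 10, 97565128 to 97572703) was lower (0.445 against 276 CPM, -8.96 ± 0.34, adjusted p = 9.8e-11). The somite factor Meox2 (-9.12 ± 0.81), the endothelin receptor Ednrb (-9.30 ± 0.57), the chemokine Cxcl2 (-9.18 ± 0.54), elastin Eln (-8.03 ± 0.68) and the cartilage genes Cnmd (-8.57 ± 0.57) and Hapln1 (-8.42 ± 0.61) were lower too, as were Gimap6, Kera and Magel2. Myf5 was higher (3.71 ± 0.61, adjusted p = 0.0004). Pax3 passed as well (1.70 ± 0.47, adjusted p = 0.014), with 331 CPM in iPax3 but 2.30 in iPax7, and its call was lost with no low-count filter (1.73, adjusted p = 0.054). Pax7 did not pass (-1.42 ± 0.75, adjusted p = 0.17), with 0.210 CPM in iPax3 and 154 in iPax7, of which the library labelled iPax7 replicate 1 held 0.989. Myod1 and Myog did not pass either (adjusted p = 0.38 and 0.35).

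Positional and matrix genes were lower in the PSC-derived cells. Of 37 measured Hox genes, which set position along the body axis, 30 fell and 0 rose (31 adjusted over the list alone), such as Hoxa9 (-7.75 ± 0.53) and Hoxa10 (-7.61 ± 0.56; camera adjusted p = 7.9e-23, list median -6.22, or -6.48 with genes at 0 set to their bound). Of 41 extracellular matrix genes, 24 fell and 3 rose (26 and 3 adjusted over the list alone), with Lama4 at -5.81 ± 0.40 and Col1a2 at -5.31 ± 0.38. Markers of other cell types moved with them: 18 of 20 tendon and cartilage markers fell (Col2a1 at -7.62 ± 0.39), 17 of 18 endothelial markers fell (Cdh5 at -7.94 ± 0.65), and 16 of 22 fibroblast markers fell while 2 rose. Immune markers fell in 13 of 22 cases with 1 higher (Ptprc at -7.91 ± 0.84), neural and Schwann markers in 10 of 21, and erythroid markers in 4 of 13 with 1 higher. All 6 of these marker lists were called down by camera, and the erythroid call was lost with an estimated correlation (adjusted p = 0.064).

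Immediate early and dissociation genes, which respond within minutes to cell handling, fell in 20 of 25 cases (21 adjusted over the list alone), with Fosb at -6.45 ± 0.37 and Fos at -6.01 ± 0.39 (camera adjusted p = 2.4e-12). Notch pathway genes fell in 5 of 20 and rose in 2 (camera adjusted p = 0.00046), with Hey1 at -3.62 ± 0.41 and Jag1 at -3.84 ± 0.46. Imprinted genes fell in 11 of 28 and rose in 2 (camera adjusted p = 1.3e-06; adjusted p = 0.064 with an estimated correlation), led by the noncoding RNAs Meg3 (-3.97 ± 0.19) and Rian (-3.65 ± 0.22). Oxidative metabolism genes rose in 23 of 31 and fell in 1 (camera adjusted p = 7.2e-08), with the ATP synthase subunit Atp5b at 1.99 ± 0.13. Cell cycle genes rose in 20 of 37 (23 up and 1 down adjusted over the list alone), with Ccne1 at 2.37 ± 0.23 (camera adjusted p = 0.00037; adjusted p = 0.47 with an estimated correlation). BMP, TGF-beta and Wnt targets fell in 5 of 19 (camera adjusted p = 0.014; adjusted p = 0.18 with an estimated correlation), and pericyte markers fell in 7 and rose in 3 of 13 (0.00061; adjusted p = 0.10 with an estimated correlation).

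Muscle lists were mixed. Myogenic regulators rose in 7 and fell in 6 of 23 (camera adjusted p = 0.034, down; adjusted p = 0.47 with an estimated correlation), and the members that fell furthest were the migration and lineage factors Lbx1 (-7.56 ± 1.20), Sim1 (-6.87 ± 1.18) and Msc (-6.10 ± 1.24). Satellite cell markers rose in 5 and fell in 7 of 28, with Cd34 at -5.32 ± 0.64. Their test pointed down (camera adjusted p = 0.034; adjusted p = 0.47 with an estimated correlation) while their median was 0.09, which turned to -0.04 with RLE size factors. Lists that camera did not call were contractile genes (13 of 43 higher, 0 lower, adjusted p = 0.079), glycolysis genes (14 higher and 3 lower of 28, 0.29), pluripotency genes (9 of 14 higher, 0.22; 4 higher and 1 lower without the library labelled iPax7 replicate 1, 0.53), epithelial markers (5 higher and 2 lower of 14, 0.22), CDK inhibitors (3 higher and 1 lower of 7, 0.22), the fetal myogenic programme (4 of 14 lower, 0.054), embryonic and oncofetal genes (4 higher and 6 lower of 20, 0.12), antigen presentation genes (4 higher and 3 lower of 25, 0.28) and cholesterol synthesis genes (1 higher and 4 lower of 21, 0.39). The pluripotency list had a mean log2 CPM of 7.96 in the library labelled iPax7 replicate 1, against -1.15 to 1.34 in the other 5 PSC-derived libraries and -1.84 to 0.106 in tissue-derived ones. Without that library camera did not call myogenic regulators (adjusted p = 0.44) or satellite cell markers (0.42), and it called contractile genes up (17 of 43 higher, 5.7e-05; adjusted p = 0.15 with an estimated correlation) and oncofetal genes down (4 higher and 7 lower of 20, 0.011; adjusted p = 0.19 with an estimated correlation). In the fetal programme the nuclear factor genes Nfib (-3.55 ± 0.46), Nfia (-3.10 ± 0.59) and Nfix (-2.95 ± 0.60) were lower.

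Across 17571 tested genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4943 genes in the contrast of PSC-derived with tissue-derived cells, 2886 higher and 2057 lower. It called 4711 without the library labelled iPax7 replicate 1, and the calls of Cxcl2 and Kera were lost when counts were thinned to the shallowest library. Of 17 lists called by camera, 10 were also called with an estimated correlation. Culture, cell purity and developmental stage differed together between these groups.

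**Figure D2:**
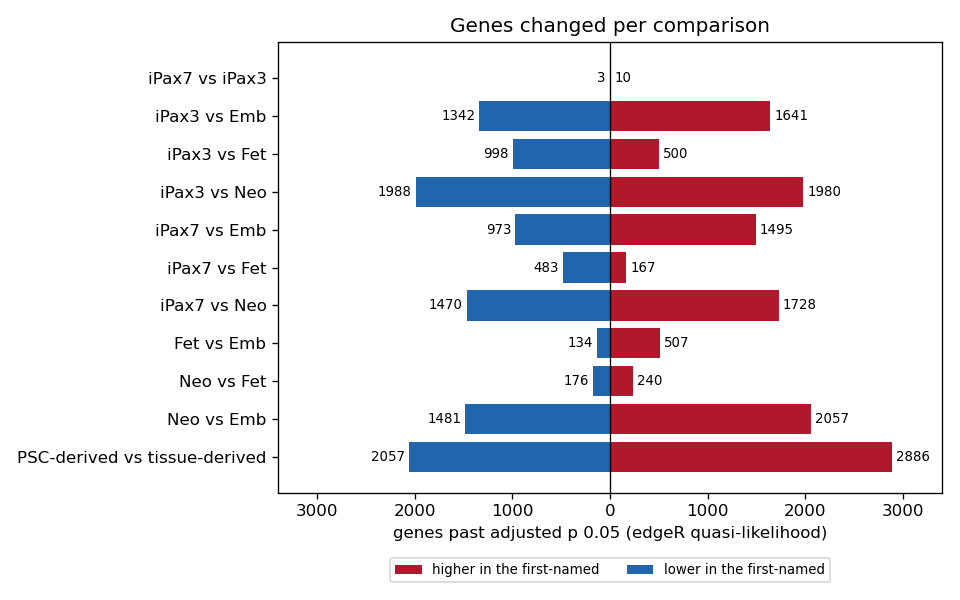
Number of genes higher and lower in each of the 11 bulk comparisons at an adjusted p of 0.05 (edgeR quasi-likelihood test, 17571 genes tested, 3 libraries per group), with the count written on each bar. The contrast of iPax7 with iPax3 had 13 changed genes, and that of PSC-derived with tissue-derived cells had 4943.

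Comparing iPax7 with iPax3 asked how the inducing factor set progenitors apart. Pax7 was higher in iPax7 (log2 fold change 9.47 ± 1.54, adjusted p = 0.028) and Pax3 lower (-7.16 ± 0.90, adjusted p = 0.0050). Both genes name the groups, so their difference is not independent of how the cells were made. Pax7 stood at 111 and 349 CPM in iPax7 replicates 2 and 3, while the library labelled iPax7 replicate 1 held it at 0.989 CPM, from 27 counts. The fibrillar collagen Col1a2 (652 against 36.7 CPM, 4.15 ± 0.52), the proteoglycan Bgn (3.19 ± 0.56), the retinoic acid carrier Crabp2 (3.00 ± 0.47), the nucleoside transporter Slc29a1 (2.76 ± 0.46) and the imprinted RNAs Rian (1.91 ± 0.30) and Meg3 (1.68 ± 0.25) were higher. The laminin chain Lama4 (3.07 ± 0.51) and the calcification inhibitor Mgp (3.22 ± 0.57), which passed the test but not the naming rule, were higher as well. The cyclin Ccnd1 (98.4 against 513 CPM, -2.38 ± 0.31) and the EGFR feedback inhibitor Errfi1 (-2.68 ± 0.42) were lower. Myf5 (-2.11 ± 0.92, adjusted p = 0.76), Myod1 (2.18 ± 1.37) and Myog (2.44 ± 1.17, adjusted p = 0.84) did not pass.

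Extracellular matrix genes were higher in iPax7 as a list (3 of 41 over all genes, 19 up and 3 down adjusted over the list alone; camera adjusted p = 2.0e-09), a call lost with an estimated correlation (adjusted p = 0.37). Fibroblast markers moved with them (1 of 22 passed, Mgp; camera adjusted p = 0.034; adjusted p = 0.45 with an estimated correlation), as did pericyte markers (0 of 13; 0.0065; adjusted p = 0.45). Contractile genes had a median of 1.59 with 0 of 43 members past the test (camera adjusted p = 0.0016; adjusted p = 0.60 with an estimated correlation), and satellite cell markers a median of 0.70 with Pax7 alone past it (0.023; adjusted p = 0.52). Pluripotency genes had a median of 6.56 with 0 of 14 past the test over all genes and 11 adjusted over the list alone (camera adjusted p = 0.00013; adjusted p = 0.45 with an estimated correlation), and this drew on the library labelled iPax7 replicate 1. Without that library, camera called contractile genes (median 2.09, adjusted p = 7.6e-24, and 0.014 with an estimated correlation), satellite cell markers (1.9e-09, and 0.014) and imprinted genes (1.2e-10, and 0.014) up, and pluripotency genes were not called (0.056). Contractile genes averaged 1.41 log2 CPM in iPax3 replicate 3, against 3.61 and 3.69 in the other iPax3 libraries and 5.37 and 5.32 in iPax7 replicates 2 and 3, and Myod1 stood at 0.264 CPM in that iPax3 library, against 9.35 and 6.05. Hox, imprinted, antigen presentation and cholesterol synthesis genes were also called up, and immediate early genes down, by camera with all libraries, each with an adjusted p of 0.45 with an estimated correlation, and the calls of Hox (0.24), antigen presentation (0.33) and cholesterol synthesis genes (0.090) were lost without that library.

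The test called 13 genes between iPax7 and iPax3, 10 higher and 3 lower, with 1083 at an unadjusted p under 0.05, and DESeq2 called 251. The count was 40 without the library labelled iPax7 replicate 1 (Pax7 at 10.04 ± 0.88, adjusted p = 6.0e-05), 28 without iPax7 replicate 2, and 6, 8 and 3 without iPax3 replicates 1, 2 and 3. The model of these 2 groups alone called 0 genes (adjusted p = 0.35 for Pax7 and 0.18 for Pax3). The Pax7 call was also lost with no low-count filter (0.15), a replicate block (0.094) or thinned counts (0.12), and without any 1 of the iPax3 replicates (log2 9.72, 9.39 and 9.29). Without any 1 of those the same went for Bgn (3.62, 3.08, 2.91), Crabp2 (3.09, 3.00, 2.90) and Slc29a1 (2.74, 2.69, 2.83). Col1a2 and Bgn were lost with no low-count filter and Crabp2, Slc29a1 and Errfi1 with a replicate block. Bgn was also lost without iPax7 replicate 1 (2.97) or 2 (3.14), Rian and Meg3 without iPax3 replicate 2 (1.86 and 1.66) or 3 (1.61 and 1.5), and Errfi1 without iPax3 replicate 3 (-2.32) or iPax7 replicate 3 (-2.37). In simulated counts, whose spread per gene was estimated over all 15 libraries and not over this pair, the test recovered 24% of 4-fold and 58% of 16-fold changes. A gene that did not pass was therefore not shown to be alike.

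Set beside Emb, of untested purity, iPax3 cells were lower in the Hox, neural and Schwann, tendon and cartilage, and fibroblast lists. Only these 4 passed with an estimated correlation. The galectin Lgals3 stood at 91.8 CPM in iPax3 with 0 counts in Emb (at least 1347-fold higher, adjusted p = 9.8e-05), and Crip2, Gprc5a, Tmprss11f and Ptk2b were at least 959, 906, 851 and 563-fold higher. The neuronal genes Ppp1r17 (54.8 CPM in Emb) and Pou3f2, the sclerotome factor Uncx, the posterior limb gene Hoxd10 and the morphogen Shh had 0 counts in iPax3 and were at least 2502, 2284, 2128, 1326 and 1223-fold lower. Pax7 was lower in iPax3 (-7.00 ± 1.4, adjusted p = 0.0037) and Myf5 higher (3.17 ± 0.96, adjusted p = 0.034). Pax3 did not pass (1.79 ± 0.70, adjusted p = 0.09), nor did Myod1 (-2.33 ± 1.38) and Myog (-2.91 ± 1.19). Hox genes fell in 27 of 37 (33 adjusted over the list alone; median -8.04, or -7.80 with genes at their bound), with Hoxa9 at -9.15 ± 0.81. Neural markers fell in 12 of 21, tendon and cartilage markers in 14 of 20 with 1 higher, and fibroblast markers in 12 of 22 with 3 higher, among them Ly6a (11.12 ± 1.49). Oxidative genes rose in 16 of 31 (22 adjusted over the list alone; camera adjusted p = 2.1e-05; adjusted p = 0.052 with an estimated correlation). Embryonic and oncofetal genes fell in 5 of 20, such as Meox1 (-6.33 ± 1.01), and 0 rose (5.9e-07; adjusted p = 0.052). Matrix genes split into 12 higher and 12 lower of 41 (camera adjusted p = 0.018; adjusted p = 0.47 with an estimated correlation), with the basement membrane proteoglycan Hspg2 at 2.98 ± 0.34 and Lama4 at -5.15 ± 0.56.

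In the contrast of iPax3 with Emb 2983 genes changed, 1641 higher and 1342 lower, and camera called 13 of 26 lists, 4 of them with an estimated correlation. The count was 5060 without Emb replicate 1 and 1492, 1669 and 1493 without iPax3 replicates 1, 2 and 3. Without any 1 library of either group the Myf5 call was lost (log2 3.04 to 3.41), as it was with no low-count filter (3.22, adjusted p = 0.12), and the Pax7 call was lost with thinned counts (-6.20, 0.068). Myog passed without Emb replicate 1 (-3.37), in fits without the library labelled iPax7 replicate 1 (adjusted p = 0.0059) or without it and Fet replicate 1 (0.0044), by DESeq2 (0.021) and in a model of the 2 groups alone (0.043), and Pax3 passed in that model (0.020) and with thinned counts (0.0049).

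In the comparison with fetal myoblasts, matrix, fibroblast, tendon and cartilage, endothelial, immune, Hox and immediate early lists were all lower in iPax3, by camera and with an estimated correlation. The matrix glycoprotein Thbs4 (0.153 against 201 CPM, -10.31 ± 1.01, adjusted p = 1.3e-05), Eln (0.274 against 315 CPM, -10.14 ± 1.06), the transporter Abca8a (-10.14 ± 0.78), Srpx (-10.27 ± 1.70) and Prelp (-10.17 ± 1.5) were lower in iPax3. Msln (250 against 0.607 CPM, 8.20 ± 1.05), Cdkn2a (7.83 ± 1.12), the adhesion receptor Selp (7.92 ± 1.43), Tmprss11f (8.36 ± 1.64) and AU018091 (7.65 ± 2.13) were higher. Pax3 (5.86 ± 0.86) and Myf5 (4.75 ± 1.06) were higher and Pax7 lower (-7.64 ± 1.44), while Myod1 (-3.20 ± 1.44) and Myog (-2.72 ± 1.19) did not pass. Matrix genes fell in 23 of 41 with 1 higher (26 and 1 adjusted over the list alone; camera adjusted p = 1.4e-20). Fibroblast markers fell in 16 of 22 with 1 higher, tendon and cartilage markers in 17 of 20, endothelial markers in 13 of 18 and immune markers in 11 of 22. Hox genes fell in 18 of 37 and immediate early genes in 15 of 25 with 1 higher, among them Fos at -6.32 ± 0.56. The fetal programme fell in 3 of 14, namely Nfib (-4.64 ± 0.71), Nfix (-4.70 ± 0.96) and Nfia (-3.93 ± 0.90; camera adjusted p = 0.0088; adjusted p = 0.38 with an estimated correlation). Satellite cell markers fell in 7 of 28 with 1 higher (camera adjusted p = 0.010; adjusted p = 0.38 with an estimated correlation). Oxidative genes rose in 12 of 31 with 1 lower (camera adjusted p = 3.6e-07).

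The test called 1498 genes between iPax3 and Fet, 500 higher and 998 lower, DESeq2 called 2784, and camera called 16 of 26 lists, 12 of them with an estimated correlation. The count fell to 886, 812 and 733 without Fet replicates 1, 2 and 3 and to 662, 899 and 624 without iPax3 replicates 1, 2 and 3. The Tmprss11f call was lost without Fet replicate 2 (8.23), that of Myf5 without Fet replicate 2 (4.84) or 3 (4.61) or with no low-count filter (4.79), and that of AU018091 without any 1 library other than iPax3 replicate 2 (6.98 to 7.96) or with a replicate block (6.81). Myog passed by DESeq2 (adjusted p = 0.039), in fits without the library labelled iPax7 replicate 1 (0.012) or without it and Fet replicate 1 (0.031) and in a model of the 2 groups alone (0.0019), and Myod1 passed in that model (0.036) and with thinned counts (0.032). Fet replicate 1 held 516504 counts, the fewest of the 15 libraries.

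Against the libraries labelled Neo, with Pax7 at 0.495 to 5.12 CPM, the immediate early, endothelial and immune lists were lower in iPax3, calls that were also made with an estimated correlation (adjusted p = 0.00051, 0.016 and 0.0046). Cdkn2a (101 CPM), the cytokine Mif, Tmprss11f, Nme4 and the cranial mesoderm factor Tbx1 had 0 counts in Neo and were at least 797, 579, 456, 283 and 276-fold higher in iPax3. The neutrophil genes Mmp8, S100a9 and Trem1 and the adiponectin relative C1qtnf9 had 0 counts in iPax3 and were at least 6085, 5090, 3520 and 5216-fold lower, and Cxcl2 was lower (-14.49 ± 0.83, 0.0138 against 467 CPM). Pax3 (8.19 ± 0.98, adjusted p = 3.4e-05) and Myf5 (6.37 ± 1.14, adjusted p = 0.0012) were higher and Pax7 lower (-3.82 ± 1.27, adjusted p = 0.042). Myod1 (adjusted p = 0.61) and Myog (0.55) did not pass. Cell cycle genes rose in 21 of 37, with Ccne1 at 4.60 ± 0.41 (camera adjusted p = 2.5e-08; adjusted p = 0.19 with an estimated correlation). Among oncofetal genes, which camera did not call (0.66), Hmga2 (5.69 ± 0.62) and Igf2bp1 (5.29 ± 0.62) were higher. Immediate early genes fell in 21 of 25 (Hspa1a at -11.13 ± 0.65), antigen presentation genes in 9 of 25, Notch genes in 8 of 20 with 1 higher, and satellite cell markers in 9 of 28 with 1 higher (camera adjusted p = 0.0028; adjusted p = 0.26 with an estimated correlation). Matrix genes fell in 33 of 41, endothelial markers in all 18, immune markers in 17 of 22, fibroblast markers in 16 of 22 and erythroid markers in 8 of 13. Contractile genes rose in 12 of 43 and fell in 1, which camera did not call (0.090).

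In this contrast of iPax3 with Neo 3968 genes changed, 1980 higher and 1988 lower, and camera called 17 of 26 lists, 12 of them with an estimated correlation. The count was 2088, 2493 and 2002 without iPax3 replicates 1, 2 and 3. The Pax7 call was lost without any 1 of iPax3 replicates 1, 2 and 3 (-4.05, -3.72 and -3.63) or without Neo replicate 2 (-3.50) or 3 (-3.30), and with no low-count filter (adjusted p = 0.13), a replicate block (0.088) or thinned counts (0.41), and that of Tbx1 without iPax3 replicate 3 or any 1 Neo library.

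For iPax7 against Emb, the 5 genes that the naming rule put highest, Dppa5a, Tdgf1, Trap1a, Fabp3 and Chchd10, had 0 counts in Emb and were at least 5299, 5002, 2305, 1138 and 828-fold higher. Dppa5a and Tdgf1 are pluripotency-associated, and the SD of all 5 in iPax7 exceeded their mean. The library labelled iPax7 replicate 1 held Trap1a at 452 CPM and Fabp3 at 223, against at most 17.9 and 7.74 in the other PSC-derived libraries. Without that library the calls of Dppa5a (6.4) and Tdgf1 (5.60) were lost, and without it and Fet replicate 1 that of Fabp3 (9.74, adjusted p = 0.060). Ppp1r17 and Shh had 0 counts in iPax7 and were at least 1360 and 665-fold lower, and the neuronal Myt1 (-10.93 ± 2.02), Trim9 (-10.79 ± 1.97) and Hoxd10 (-10.62 ± 2.48) were lower. Pax3 was lower (-5.37 ± 0.83, adjusted p = 0.00074), and Pax7 (2.47 ± 1.12, adjusted p = 0.15), Myf5, Myod1 and Myog did not pass. Hox genes fell in 23 of 37 (median -6.90), neural markers in 9 of 21 and tendon and cartilage markers in 10 of 20 with 1 higher. Contractile genes rose in 8 of 43, such as the fast light chain Mylpf (4.54 ± 0.95; camera adjusted p = 0.046; adjusted p = 0.90 with an estimated correlation). Oxidative genes rose in 17 of 31 (5.7e-05; adjusted p = 0.063), and antigen presentation genes rose in 7 of 25 (0.0075; adjusted p = 0.28). Myogenic regulators fell in 5 of 23 and rose in 2 (0.00026; adjusted p = 0.28), with the placodal factor Eya1 at -3.33 ± 0.56, and were not called without the library labelled iPax7 replicate 1 (5 higher and 4 lower, 0.27). Fibroblast markers fell in 10 and rose in 4 of 22 (0.00026; adjusted p = 0.061), and matrix genes rose in 12 and fell in 4 of 41 (0.92).

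The test called 2468 genes between iPax7 and Emb, 1495 higher and 973 lower, and DESeq2 called 4003. The count was 4810 without Emb replicate 1, 1436 and 1373 without Emb replicates 2 and 3, 1436 and 1301 without iPax7 replicates 2 and 3, and 2129 without the library labelled iPax7 replicate 1, where Pax7 (3.06) and Myf5 (1.65) passed. Dppa5a and Tdgf1 were also lost without Emb replicate 2 or 3 and with a replicate block, and these 2 and Trap1a (adjusted p = 0.056) with no low-count filter. Trap1a (0.11), Fabp3 (0.11) and Chchd10 (0.062) were lost in a model of the 2 groups alone, and Hoxd10 without iPax7 replicate 3 (-10.24) or without both the library labelled iPax7 replicate 1 and Fet replicate 1 (-10.19). Camera called 12 of 26 lists, 3 of them with an estimated correlation.

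Between iPax7 and Fet, the CDK inhibitors Cdkn2a (7.45 ± 1.11, 77.9 against 0.295 CPM, adjusted p = 0.0010), Cdkn2b (6.58 ± 1.68) and Cdkn1a (3.07 ± 0.58) were higher in iPax7. These were the 3 of 7 in the list that rose (camera adjusted p = 0.017; adjusted p = 0.080 with an estimated correlation). The metallothionein Mt2 (6.84 ± 0.99), Pkp2 (7.17 ± 1.44) and Msln (6.54 ± 0.99) were higher as well. The angiotensin receptor Agtr2 (0.300 against 371 CPM, -10.26 ± 0.90), the dermal matrix gene Dpt (-10.12 ± 1.04), Cnmd (-10.10 ± 0.87) and the embryonic globin Hbb-y (-10.68 ± 2.71) were lower, and the endothelial Emcn had 0 counts in iPax7 (at least 623-fold lower). None of Pax3, Pax7, Myf5, Myod1 and Myog passed the edgeR test (adjusted p = 0.40, 0.45, 0.16, 0.79 and 0.95). Matrix genes fell in 19 of 41 (25 adjusted over the list alone), tendon and cartilage markers in 16 of 20, fibroblast markers in 13 of 22, endothelial markers in 8 of 18 and immune markers in 4 of 22 (14 adjusted over the list alone). Hox genes fell in 9 of 37 (27 adjusted over the list alone), immediate early genes in 12 of 25 and imprinted genes in 8 of 28. The fetal programme fell in 2 of 14, Nfib (-3.98 ± 0.69) and Nfia (-3.37 ± 0.88; camera adjusted p = 0.0035; adjusted p = 0.31 with an estimated correlation), and was not called without the library labelled iPax7 replicate 1 (0.16).

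In the contrast of iPax7 with Fet 650 genes changed, 167 higher and 483 lower, and DESeq2 called 1732. The count was 412, 374 and 353 without Fet replicates 1, 2 and 3, and 731 without the library labelled iPax7 replicate 1, where Pax7 (2.43) and Myf5 (3.23) passed. Calls were lost for Pkp2 without Fet replicate 2 (6.70), for Cdkn2b without any 1 library other than iPax7 replicate 1 (6.08 to 6.77), and for Hbb-y without any 1 library other than Fet replicate 1 (-12.32 to -10.21) or with thinned counts (-7.04). A replicate block ended the calls of Cdkn2b and Hbb-y too (adjusted p = 0.058 and 0.076). Camera called 18 of 26 lists, 10 of them with an estimated correlation.

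Relative to the libraries labelled Neo, iPax7 cells had more Pax7 (5.64 ± 1.32, adjusted p = 0.0094) and Myf5 (4.26 ± 1.04, adjusted p = 0.012), while Pax3 (1.03 ± 0.84), Myod1 and Myog did not pass. Mif (120 CPM) and Cdkn2a (77.9 CPM) had 0 counts in Neo and were at least 946 and 613-fold higher. Dppa5a, Tdgf1 and the growth factor Fgf4 were at least 2839, 2680 and 701-fold higher, and the calls of all 3 were lost without the library labelled iPax7 replicate 1 (6.4, 5.60 and 5.05). Cxcl2 (-14.58 ± 0.86) was lower, and Mmp8, S100a9, Emcn and the leukocyte antigen Ptprc had 0 counts in iPax7 and were at least 3307, 2766, 2213 and 2068-fold lower. Contractile genes rose in 17 of 43 (24 up and 1 down adjusted over the list alone), such as Myh3 (6.09 ± 1.4; camera adjusted p = 0.0017; adjusted p = 0.50 with an estimated correlation). Cell cycle genes rose in 24 of 37 (camera adjusted p = 1.7e-08; adjusted p = 0.20 with an estimated correlation) and oxidative genes in 19 of 31 with 1 lower. Immediate early genes fell in 20 of 25, matrix genes in 32 of 41 with 1 higher, Hox genes in 17 of 37 and Notch genes in 6 of 20 with 1 higher. Endothelial markers fell in 16 of 18, immune markers in 16 of 22 and fibroblast markers in 15 of 22. Imprinted genes, called down by camera (0.00074; adjusted p = 0.19), had a median of -0.33 that turned to 0.13 when the 20 most abundant genes were left out, and were not called without the library labelled iPax7 replicate 1 (0.070).

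The test called 3198 genes between iPax7 and Neo, 1728 higher and 1470 lower, and 2047 without iPax7 replicate 3. The calls of Pax7 and Myf5 were lost in a model of the 2 groups alone (adjusted p = 0.067 and 0.084) and that of Myf5 with no low-count filter (0.056). The library labelled iPax7 replicate 1 held Pax7 at 0.989 and Myf5 at 1.10 CPM, within the Neo ranges of 0.495 to 5.12 and 0.816 to 6.32 CPM. Dppa5a and Tdgf1 were also lost without any 1 Neo library and Fgf4 without Neo replicate 1 or 2, all 3 with no low-count filter or a replicate block, and Pax3 passed without Neo replicate 3 (3.09). Camera called 18 of 26 lists, 10 of them with an estimated correlation.

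From Emb to Fet, matrix, fibroblast, and tendon and cartilage lists rose and the oncofetal list fell. Stage and purity were not separated. The serine protease Htra1 (50.2 against 0.0681 CPM, 9.40 ± 0.75, adjusted p = 4.3e-06), the mast cell protease Cpa3 (11.79 ± 1.19), the metalloprotease Adam33 (9.45 ± 1.03), the transglutaminase subunit F13a1 (8.92 ± 1.04), the cartilage genes Matn1 and Col10a1, and Il1rl1, Tnn and mt-Atp8 were higher in Fet, and Clec3b had 0 counts in Emb (at least 322-fold higher). The chromatin protein Hmga2 (100.1 against 1105 CPM, -3.48 ± 0.56), the Lin28 partner Trim71 (-4.57 ± 1.08), the adhesion molecules Cadm1 (-2.63 ± 0.35) and Igsf9 (-2.92 ± 0.45), the glycolytic Pgam1 (-3.14 ± 0.61), Ppp1r17, Pou3f2, Mir296 and Pfdn4 were lower. Pax3 was lower (-4.07 ± 0.80, adjusted p = 0.011), and Pax7 (0.64 ± 1.08), Myf5, Myod1 and Myog did not pass. Matrix genes rose in 27 of 41 (36 adjusted over the list alone; camera adjusted p = 3.2e-20), with Col5a3 at 7.47 ± 0.74. Fibroblast markers rose in 10 of 22, tendon and cartilage markers in 8 of 20, immune markers in 7 of 22 and endothelial markers in 5 of 18 (camera adjusted p = 8.5e-09; adjusted p = 0.10 with an estimated correlation). Immediate early genes rose in 13 of 25, with Junb at 6.69 ± 0.50. Oncofetal genes fell in 3 of 20 (9 adjusted over the list alone; camera adjusted p = 1.8e-07). Of the fetal programme 1 of 14 rose, Nfix (3.58 ± 0.91; camera adjusted p = 0.0093; adjusted p = 0.40 with an estimated correlation). Cell cycle genes (0 of 37 passed; 0.0022; adjusted p = 0.53) and Hox genes (0 of 37; 6.2e-06; adjusted p = 0.064) were called down by camera.

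In the contrast of Fet with Emb 641 genes changed, 507 higher and 134 lower, DESeq2 called 2174, and camera called 16 lists, 6 of them with an estimated correlation. The count was 2843 without Emb replicate 1, 319 and 295 without Emb replicates 2 and 3, 383, 233 and 244 without Fet replicates 1, 2 and 3, and 1010 in a fit without the library labelled iPax7 replicate 1. The Pax3 call was lost without Fet replicate 2 (-4.26) or 3 (-4.18) or with no low-count filter (-4.06, adjusted p = 0.057), and that of Pgam1 without Fet replicate 2 (-3.20) or with no low-count filter (-3.13). A model of the 2 groups alone ended the calls of mt-Atp8 (9.90, adjusted p = 0.058), Mir296 (0.058) and Pfdn4 (0.075). No low-count filter also ended those of Trim71 (0.11), Mir296 (0.056) and Pfdn4 (0.054), scaling by total counts that of Pfdn4 (0.0505), and a replicate block those of Ppp1r17 (0.0504), Pou3f2 (0.085), Trim71 (0.068), Mir296 (0.086) and Pfdn4 (0.084). Trim71, Pou3f2, Mir296, Pfdn4 and Col10a1 were lost without any 1 Fet library, and all 5 without Emb replicate 2. Ppp1r17 was lost without Emb replicate 2 (-6.23) or Fet replicate 2 (-6.92) or 3 (-6.22), and Pou3f2, Mir296, Pfdn4 and Col10a1 also without Emb replicate 3.

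Comparing the libraries labelled Neo, with Pax7 at 0.495 to 5.12 CPM, with fetal myoblasts at 32.6 to 55.3, the lists of immediate early and dissociation genes and of antigen presentation genes were higher in Neo, the 2 lists also called with an estimated correlation (adjusted p = 0.00042 and 0.036). The heat shock gene Hspa1a (8.40 ± 0.61, adjusted p = 2.9e-06) led the 13 of 25 immediate early and dissociation genes that rose (20 adjusted over the list alone; camera adjusted p = 1.2e-20). The lectin Clec4d (8.02 ± 1.10), Mmp8 (8.20 ± 1.22), Trem1, S100a9, Rnd1 and Selp were higher, and Igll1, Retnlg and Hemgn had 0 counts in Fet (at least 473, 447 and 448-fold higher). The kinesin Kif26b, Bex4 and Mif had 0 counts in Neo and were at least 210, 183 and 168-fold lower. The neural and dermomyotome factor Zic1 (-6.32 ± 1.02), the cardiac actin Actc1 (-6.53 ± 1.4), nebulin Neb (-6.36 ± 1.33), Rps6ka6 (-5.55 ± 0.92), Snhg11, Syt13 and Crabp1 were lower. Pax7 did not pass (-3.81 ± 1.23, adjusted p = 0.11), nor did Pax3 (0.15), Myf5 (0.42), Myod1 (0.44) and Myog (0.47). Cell cycle genes fell in 9 of 37 (20 adjusted over the list alone; camera adjusted p = 2.1e-07; adjusted p = 0.32 with an estimated correlation). Contractile genes fell in 4 of 43 and rose in 1, the adult actin Acta1 (0.0023; adjusted p = 0.50). Antigen presentation genes rose in 4 of 25 (camera adjusted p = 4.3e-10), and oncofetal genes fell in 6 of 20, such as Igf2bp1 (-4.59 ± 0.61; camera adjusted p = 0.024; adjusted p = 0.33 with an estimated correlation). Endothelial markers rose in 2 of 18 (1.7e-09; adjusted p = 0.13), immune markers in 1 of 22 (7.5e-07; adjusted p = 0.10) and erythroid markers in 1 of 13 (7.7e-06; adjusted p = 0.17).

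The test called 416 genes between Neo and Fet, 240 higher and 176 lower, and DESeq2 called 1662. The count was 241, 86 and 131 without Fet replicates 1, 2 and 3, 183 and 161 without Neo replicates 1 and 2, and 751 in a fit without the library labelled iPax7 replicate 1. The calls of Igll1, Hemgn and Snhg11 were lost without any 1 library, those of Bex4 and Crabp1 without any 1 other than Fet replicate 1, and that of Retnlg without any 1 Fet library or Neo replicate 2. Those of Syt13 (-7.51 to -6.68) and Neb (-6.49 to -5.72) were lost without Fet replicate 2 or 3 or Neo replicate 1 or 2, and that of Actc1 (-6.61 to -5.90) without Fet replicate 2 or 3 or Neo replicate 1 or 3. Mmp8 was lost without Fet replicate 2 (7.90) or Neo replicate 2 (6.64), Trem1 without any 1 Fet library (7.28 to 9.14) or Neo replicate 2 (6.37), and S100a9 without Fet replicate 1 (7.58) or Neo replicate 1 (7.94) or 2 (6.83). Rnd1 was lost without Fet replicate 2 (7.41) and Selp without Fet replicate 2 (7.07) or 3 (7.71). No low-count filter also ended the calls of Snhg11 (adjusted p = 0.14), Actc1 (0.10) and Selp (0.066), a replicate block those of Hemgn (0.11), Retnlg (0.071), Snhg11 (0.067), Igll1 (0.061) and S100a9 (0.051), thinned counts that of Bex4 (0.080) and DESeq2 that of Hemgn (0.20). Pax3 passed without Neo replicate 3 (-4.37). Pax7 passed by DESeq2 (adjusted p = 0.013), in fits without the library labelled iPax7 replicate 1 (0.0039) or without it and Fet replicate 1 (0.014) and in a model of the 2 groups alone (0.015), where Myog passed too (0.023). Camera called 15 lists, 2 of them with an estimated correlation.

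From E10.5 to postnatal day 3, Clec3b, the endothelial amine oxidase Aoc3, Crip2 and the interferon-induced chemokine Cxcl10 were at 0 counts in Emb and at least 1255, 1203, 884 and 623-fold higher in the libraries labelled Neo, which held Pax7 at 0.495 to 5.12 CPM. Arhgap30, Edn1, Stfa1, Gimap4 and Samd9l, at 0 counts in Emb, were at least 834, 833, 700, 677 and 629-fold higher. Mif, Kif26b, the laminin chain Lama1 and the neural proteoglycan Ncan had 0 counts in Neo and were at least 436, 405, 332 and 262-fold lower, and the sensory neuron factor Pou4f1 was lower (-10.32 ± 1.68). Pax3 (-6.40 ± 0.92, adjusted p = 0.00027) and Myf5 (-3.20 ± 1.0, adjusted p = 0.037) were lower, while Pax7 (-3.17 ± 1.19, adjusted p = 0.070), Myod1 (0.54) and Myog (0.26) did not pass. Matrix genes rose in 36 of 41 and immediate early genes in 24 of 25, with Junb at 9.45 ± 0.56. Antigen presentation genes rose in 17 of 25 (median 6.45, or 5.72 with genes at their bound). Markers of other cell types rose alongside: 17 of 22 immune, 15 of 18 endothelial, 12 of 22 fibroblast, 11 of 20 tendon and cartilage and 10 of 13 erythroid (camera adjusted p = 1.1e-06; adjusted p = 0.077 with an estimated correlation). Satellite cell markers rose in 8 of 28 and fell in 1 (camera adjusted p = 0.029; adjusted p = 0.47 with an estimated correlation), among them Cav1 (9.46 ± 0.56), which endothelial cells also express. The fetal programme rose in 4 of 14 and fell in 1 (0.046; adjusted p = 0.48), with Nfix at 4.39 ± 0.94. Oncofetal genes fell in 10 of 20, such as Hmga2 (-6.04 ± 0.63), neural markers in 9 of 21 with 1 higher, and cell cycle genes in 22 of 37 (camera adjusted p = 2.7e-10; adjusted p = 0.16 with an estimated correlation).

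In the contrast of Neo with Emb 3538 genes changed, 2057 higher and 1481 lower, and camera called 18 of 26 lists, 9 of them with an estimated correlation. The Myf5 call was lost without Emb replicate 2 (-3.25) or 3 (-2.94) or Neo replicate 1 (-3.05) or 2 (-2.73), and with no low-count filter (adjusted p = 0.11), a replicate block (0.053), a model of the 2 groups alone (0.16) or thinned counts (0.062). In fits without the library labelled iPax7 replicate 1, or without it and Fet replicate 1, Pax7 (-3.20, adjusted p = 0.0029, and 0.0052) and Myog (-1.90, 0.038, and 0.034) passed, and Pax7 passed by DESeq2 (0.025). Changing the scaling moved the median log2 fold change of all genes by over 0.1 in some contrasts: RLE size factors moved it by -0.103 in iPax3 against Emb, -0.139 against Fet, -0.232 against Neo, -0.167 in iPax7 against Neo, 0.104 in Neo against Fet and -0.122 in PSC-derived against tissue-derived cells. Scaling by total counts moved it by 0.177 in iPax3 against Neo, 0.250 in iPax7 against Neo, -0.254 in Neo against Fet and -0.157 in Neo against Emb.

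Which stage the PSC-derived cells lay nearest was compared within libraries, each correlated with the mean of every stage, where an exact two-sided sign-flip test over 3 libraries cannot give a p under 0.25. The Pearson correlation of log2 CPM across the 17571 genes, which are not independent replicates, was 0.784 ± 0.00998 (SD, n = 3) between iPax3 libraries and the Emb mean, 0.797 ± 0.0146 with Fet and 0.711 ± 0.0143 with Neo. For iPax7 it was 0.777 ± 0.0220, 0.795 ± 0.0407 and 0.708 ± 0.0332, and 0.789, 0.818 and 0.726 without the library labelled iPax7 replicate 1. The correlation with Fet exceeded that with Emb in 3 of 3 iPax3 libraries (by 0.0150, 0.0161 and 0.00716; exact p = 0.25, adjusted p = 0.30 over 6 comparisons). In iPax7 it did so in replicates 2 and 3 (by 0.0295 and 0.0286) and not in the library labelled iPax7 replicate 1 (-0.00345; exact p = 0.50). In every iPax library the correlation with Neo was the lowest (exact p = 0.25 in each group against Emb and Fet). The stages also differed in how well their own libraries correlated with each other (mean 0.783 in Emb, 0.879 in Fet and 0.798 in Neo). The order of the stages was not separated from this spread of the references. Without Fet replicate 2 the correlation with Fet was 0.777 for iPax3 and 0.775 for iPax7, below those of 0.784 and 0.777 with Emb. Without Emb replicate 1 the correlation with Emb was lower, 0.745 for iPax3 and 0.738 for iPax7. Over the 1000 most variable reference genes it was 0.265, 0.354 and -0.0749 for iPax3. Stage signatures chosen from the 9 tissue libraries alone held 108 Emb, 4 Fet and 286 Neo genes. The Emb signature averaged 8.52 log2 CPM in Emb, 6.55 in Fet, 5.81 in Neo, 5.70 in iPax3 and 5.65 in iPax7. The 4 Fet genes averaged 7.66 in Fet, 5.19 in Neo, 3.46 in Emb, 2.56 in iPax3 and 3.27 ± 1.68 (SD) in iPax7, and the Neo signature 7.90 in Neo, 4.63 in Fet, 3.08 in Emb, 3.51 in iPax3 and 3.66 in iPax7. Levels against the groups that chose the genes are not independent of the choice. None of the 3 signatures differed between iPax7 and iPax3 by camera (adjusted p = 0.520 each), and without the library labelled iPax7 replicate 1 the 4 Fet genes were higher in iPax7 (adjusted p = 0.0024). Counts of signature genes ranged from 36 to 199 (Emb), 1 to 12 (Fet) and 159 to 442 (Neo) when single libraries were left out, with 199 and 12 without Emb replicate 1, 36 without Fet replicate 3, 1 and 159 without Fet replicate 2 and 442 without Emb replicate 2.

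At single-cell level, with 1 library each and no test, 579 adult cells (median 10765 UMIs) were compared with 2931 iPax3 cells (median 11716) on UMIs summed over cells. The adult cells carried Pax7 at 146 CPM, against 0.0480 CPM from 2 UMIs in iPax3 (log2 ratio of iPax3 to adult -11.57, interval -14.62 to -9.72). Pax3 stood at 164 CPM in iPax3 and 3.29 in adult cells (5.64, 5.09 to 6.26) and Myog at 124 against 5.31 CPM (4.54, 4.10 to 5.01), while Myf5 (14.1 against 43.9 CPM, -1.64) and Myod1 (26.4 against 216 CPM, -3.03) were higher in adult cells. Intervals are exact at 95% and cover counting error only. In the deeper iPax3 sample of 3327 cells the log2 ratios were -0.91 (-1.07 to -0.75) for Myf5, -2.02 (-2.10 to -1.95) for Myod1, 5.57 (5.13 to 6.04) for Myog and -12.87 (-15.15 to -11.32) for Pax7, from 3 UMIs. The slow troponin Tnnc1 (373 against 0.126 CPM, from 1 UMI, 11.53, 9.05 to 16.83) and embryonic myosin Myh3 (153 against 0.126 CPM, 10.24) were higher in iPax3. So were Cdkn2a (354 against 0.379 CPM, 9.87, 8.32 to 12.14), Hist1h2ap and Npnt. Krt8, Hmga2, Tnni1, the growth inhibitor Mstn and Perp had 0 adult UMIs and were at least 749, 663, 661, 380 and 364-fold higher. The invariant chain Cd74 (2040 CPM, -14.05), Hspa1a (2587 CPM, -12.72), Dcn (858 CPM, -12.54), Xist, H2-Aa, Rarres2, Retnla and Aqp1 were higher in adult cells, and H2-Ab1 and the myeloid adaptor Tyrobp had 0 iPax3 UMIs and were at least 10543 and 3171-fold higher there. In the deeper sample Perp was at least 705-fold higher in iPax3, Dcn had -11.76 and Tyrobp was at least 11702-fold higher in adult cells, and H2-Ab1 had 4 UMIs in iPax3 (-14.83).

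By list, the median log2 ratio of iPax3 to adult was 5.08 for cell cycle genes (36 of 37 higher in iPax3), 2.03 for contractile genes (31 of 40) and 3.71 for the 6 epithelial markers measured, each at percentile 100 of 10000 random lists matched on expression. Members of the random lists were drawn independently, so the percentiles do not allow for list genes that vary together. It was 1.31 for imprinted genes (percentile 99.7) and 0.94 for oxidative genes (98.8). On the adult side, satellite cell markers had -3.75 (24 of 28 higher in adult cells), antigen presentation genes -5.57, immediate early genes -5.80 (all 25), Hox genes -5.36 and matrix genes -2.39 (31 of 41), each at percentile 0. Immune (-9.34), endothelial (-6.86), fibroblast (-6.68) and tendon markers (-5.67) were also at percentile 0. In the deeper iPax3 sample the median was -2.07 for tendon markers, with 17 rather than 13 genes measured (percentile 0), and 2.00 for epithelial markers, with 8 rather than 6 (99.7). Medians of Hox genes (-7.25), endothelial (-8.48) and immune markers (-10.05) lay further on the adult side there. Without the adult clusters named as other cell types, the epithelial median was 5.46, from 5 genes. In that setting immune (-9.68), endothelial (-6.57), fibroblast (-6.21) and tendon markers (-5.54) stayed at percentile 0. These lists were thus also higher in the unnamed adult cells alone than in iPax3. In the first iPax3 sample the fetal programme (-2.41, 0.02), Notch genes (-1.37, 0.3), BMP, TGF-beta and Wnt targets (-1.33, 0.01) and pericyte markers (-3.27, 0.01) were low as well. Myogenic regulators (-0.06, 29.8), oncofetal genes (0.71, 75.6), CDK inhibitors (-0.38, 21.3), glycolysis genes (0.23, 48.8), cholesterol genes (-0.27, 10.3) and neural markers (0.67, 71.9) lay inside the random range, and pluripotency and erythroid lists had 3 and 1 measured genes. In the deeper sample the medians of myogenic regulators (0.18) and cholesterol genes (0.27) changed sign, inside the random range. Medians of the random lists were 0.18 to 0.81.

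**Figure D3:**
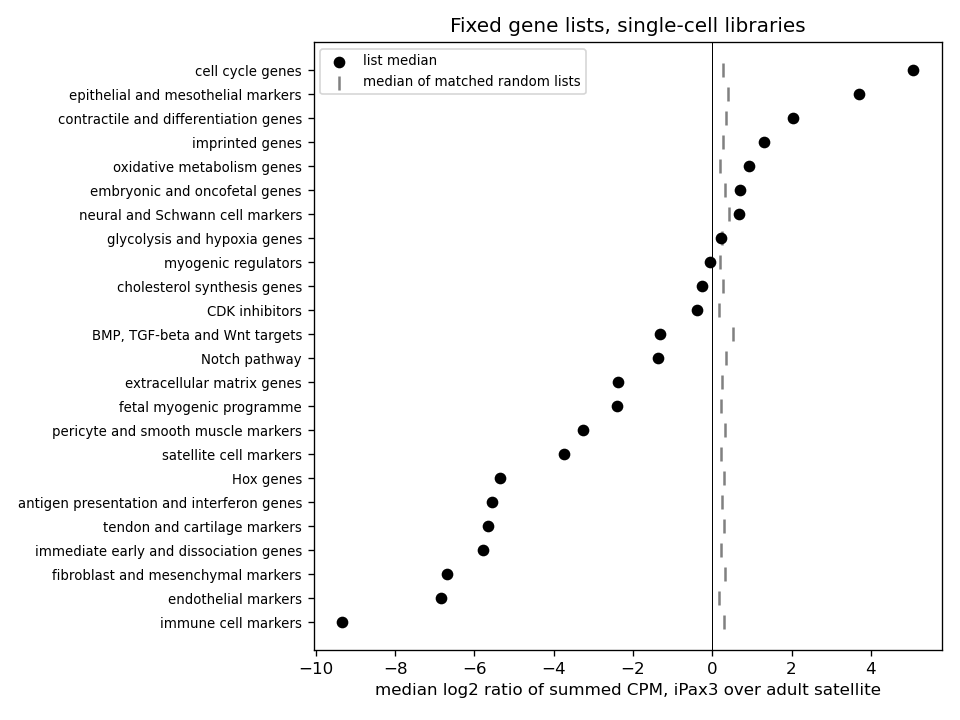
Median log2 ratio of summed CPM, iPax3 over adult satellite cells, for each fixed gene list (1 library each), with a tick for the median of 10000 matched random lists. Cell cycle genes lie at 5.08 and satellite cell markers at -3.75.

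Clustered alone, the adult cells held an endothelial-like cluster (56 cells, 9.67%, interval 7.39 to 12.4), a fibroblast-like cluster (41 cells, 7.08%, 5.13 to 9.48) and a macrophage-like cluster (21 cells, 3.63%, 2.26 to 5.49), named from fixed markers. The other 461 cells fell in 2 clusters that met no naming rule, although Pax7 was measured in every adult cluster at 123 to 155 CPM. Pecam1 stood at 127.5 CPM in the endothelial-like cluster and 21.4 to 38.6 CPM in the others. Of the iPax3 cells, 738 (25.2%, 23.6 to 26.8) lay in 2 myoblast-like clusters with Myog, Actc1, Tnnt1 and Ttn. The remaining clusters took no name: 34.2% of cells led by Krt18, Krt8 and Ly6a, 773 cells led by Scg2, Hmcn1 and Igfbp5, and 419 cells led by Nusap1, Mki67 and Col3a1. Intervals of shares are exact binomial intervals.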

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

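The tests of a swap and of missing induction for the library labelled iPax7 replicate 1, of a second whole cell in adult droplets, and of splits that keep the 5 groups whole, were chosen after the result was seen. Among 66 measures, 7 had a library far from the others of its set by Dixon's test, and chance gives about 1 in 20.

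The library labelled iPax7 replicate 1 stood apart from the other 5 PSC-derived libraries in pluripotency genes (mean log2 CPM 7.96), glycolysis genes (7.24), immune markers (-1.30) and endothelial markers (0.66), highest in each. A swap with an iPax3 library was argued against, since no iPax3 library held Pax7 above 0.280 CPM; the library correlated more with the iPax3 libraries (0.849 to 0.872) than with the other two iPax7 libraries (0.827 each), but held Pax3 at 1.10 CPM, against 295 to 355 in iPax3. A mixture of iPax7 cells with pluripotent cells could not be excluded: 3 fibroblast markers stood at a median of 20.5% of their level in the other two iPax7 libraries (range 18.7 to 100.6%), where Pax7 stood at 0.429%. A bound of 20% for the median had been set beforehand, but the value passed it by less than its spread, and the reading was therefore changed to open after it was seen. Cells in which Pax7 had not been induced remain open as well, since only the 0.429% is at hand and no uninduced library was sequenced.

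Pax7 was far higher in iPax7 replicate 3 (349.3 CPM) than in the other PSC-derived libraries, of which the next held 111 CPM. The same library had the lowest mean log2 CPM of immediate early and dissociation genes among PSC-derived libraries (2.87). Myod1 in Fet replicate 1 (84.7 CPM) was far above the other tissue-derived libraries. No explanation was tested for these 3 values.

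The second iPax3 file held 577 of the 579 adult cell barcodes, where 0.463 would be shared by chance, a signal outside the data compared. In all 577, every count was at most that of the adult sample, with a median UMI ratio of 0.699. Its other part held all 2931 iPax3 cell barcodes with a median UMI ratio of 3.47.

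Xist stood at 1856 to 2235 CPM in Emb, 1281 to 1750 in Fet and 489 to 1305 in Neo, and Ddx3y at 114 to 359 CPM in Neo and at most 1.73 in Emb and Fet. Of the 3538 genes called between Neo and Emb, 3.36% lay on X or Y, against 3.97% of tested genes, so genes on X and Y were not over-represented. This share cannot decide whether sex of the animals was the main source of the difference, since it does not cover autosomal genes. Y-linked transcripts also differed together with stage.

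Pax7 was measured in every adult cluster, also those named endothelial, fibroblast and macrophage. Free RNA was argued against, since barcodes ranked after the first 1000 and up to 3000 held a median of 0.307% of the UMIs of a median cell. Droplets with a satellite cell and a second whole cell could not be told apart from single cells: 12 satellite markers had a median ratio of 0.773 in named over unnamed clusters (range 0.497 to 1.12), between the values set for either reading. Scrublet called 2 of the 579 cells doublets, clusters of those 3 names held 57, 37 and 21 cells without them, and median UMIs were 8453.5, 9797 and 17319 in the endothelial-like, fibroblast-like and macrophage-like clusters against 7368 and 14786.5 in the 2 unnamed ones, so a second cell stays open in all 3. Reporter expression per cell is not recorded, and no biological explanation was tested.

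For the 10 pairs of groups there are 10 splits of 6 libraries, too few for a share under 0.05, and in each pair 1 split, the real one, gave as many genes. The real and highest other counts were 13 and 3 (iPax7 against iPax3), 2983 and 0, 1498 and 0, 3968 and 0 (iPax3 against Emb, Fet and Neo), 2468 and 22, 650 and 1, 3198 and 2 (iPax7 against Emb, Fet and Neo), 641 and 41 (Fet against Emb), 416 and 1 (Neo against Fet) and 3538 and 372 (Neo against Emb). For PSC-derived against tissue-derived libraries, 1 of 100 splits of single libraries, the real one, gave as many genes (4943, highest other 290), which excludes a chance assignment of single libraries. Those splits break up the groups, whose libraries resemble each other. With the 5 groups kept whole there are 10 splits, too few for a share under 0.05, and 1, the real one, gave as many genes (4943, highest other 4132, Fet and Neo against the rest).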

How the results depend on the processing

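The settings without the library labelled iPax7 replicate 1 in all comparisons, without it and Fet replicate 1, thinned, and with the deeper iPax3 sample were chosen after the data were seen; the cause was not tested for any change below unless stated. Main results stayed within a set margin in 385 settings, moved in 110 and became stronger in 5. Named genes kept sign and call in 3200, lost a call in 256, gained one in 31 and reversed in 15.

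The 13 genes of iPax7 against iPax3 became 22 with no low-count filter, 7 with a replicate block, 0 in an edgeR model of these 2 groups alone (1686 at an unadjusted p under 0.05), 31 without both libraries and 251 by DESeq2. DESeq2 gave 2784 for iPax3 against Fet, 4003 and 1732 for iPax7 against Emb and Fet, 2174 for Fet against Emb and 1662 for Neo against Fet. Models of 2 groups alone gave 6369 for iPax3 against Fet, 236 and 1866 for iPax7 against Emb and Neo, 306 for Fet against Emb, 1246 for Neo against Fet and 1496 for Neo against Emb. A replicate block gave 1517 for iPax7 against Emb, 379 for Fet against Emb and 263 for Neo against Fet. A model without the library labelled iPax7 replicate 1 gave 1010 for Fet against Emb and 751 for Neo against Fet, and thinning gave 713 for the latter.

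Leaving out 1 library at a time gave 3 to 40 genes for iPax7 against iPax3, 1492 to 5060, 624 to 899 and 2002 to 3388 for iPax3 against Emb, Fet and Neo, 1301 to 4810, 353 to 731 and 2047 to 2540 for iPax7 against them, 233 to 2843 for Fet against Emb and 86 to 337 for Neo against Fet. These models hold fewer libraries.

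Of lists, an estimated correlation called 0 in iPax7 against iPax3 (1 at an unadjusted p under 0.05), as did fry (1), 4 in iPax3 against Emb, 3, 10 and 10 in iPax7 against Emb, Fet and Neo, 6 in Fet against Emb, 2 in Neo against Fet, 9 in Neo against Emb and 10 in PSC-derived against tissue-derived cells. Leaving out 1 library gave 3 to 15 lists in iPax7 against iPax3.

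Myod1 and Myog, never called there, reversed for iPax7 against Emb to 0.0217 with total counts (Myod1) and 0.42 and 0.10 without both libraries, with ranges of -0.92 to 0.46 and -0.94 to 0.12 when 1 library was left out. For iPax7 against Fet they reversed to 0.19 and 0.62 without both libraries, with a range of -0.74 to 0.32 for Myog when 1 library was left out. Myog in Fet against Emb reversed to 0.0881 with a replicate block and 0.00171 when thinned, with a range of -0.67 to 0.32.

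Spearman correlations of iPax3 were 0.801, 0.823 and 0.738 with Emb, Fet and Neo. Over the 1000 most variable reference genes correlations were 0.265, 0.354 and -0.0749 for iPax3 and 0.270, 0.374 and -0.0762 for iPax7. Leaving out 1 library gave 0.745 to 0.789, 0.777 to 0.805 and 0.693 to 0.718 for iPax3, and 0.738 to 0.789 for iPax7 with Emb. At a log2 fold change of 2 the stage signatures held 34, 2 and 187 genes, and 36 to 199, 1 to 12 and 159 to 442 with 1 library left out. The unadjusted p of the Fet signature in iPax7 against iPax3 was 0.296, 0.0168 with RLE and 0.000806 to 0.985 with 1 library left out, and that of the Neo signature 0.390 and 0.0465 to 0.983.

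In single cells the log2 ratios in the deeper sample were -0.91 for Myf5, -2.02 for Myod1 and 5.57 for Myog, and -3.21 for Myod1 without the clusters of other cell types. At resolution 1.0, 23.4% of iPax3 cells lay in myoblast-like clusters, and 12 adult cells (2.07%) formed a cluster of that name with Tnnt3, Acta1, Myl1, Mylpf, Ckm and Tnnc2. At the main resolution of 0.5 the planned restriction to clusters named satellite cell or myoblast had no adult cells and was not run. Fet replicate 1, with 516504 counts, limits what low-abundance genes can show.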

Other observations

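The simple-epithelium keratins Krt8 and Krt18 led the largest iPax3 single-cell cluster (34.2% of cells), beside the stem cell antigen Ly6a and the AP-1 member Fosl1. In bulk, Krt8 stood at 203 CPM in PSC-derived and 0.837 CPM in tissue-derived libraries, and the summed iPax3 cells held it at 284 CPM with 0 adult UMIs. A second iPax3 cluster of 773 cells was led by the granin Scg2 and the matrix gene Hmcn1, and neither cluster met the marker rule for a cell type. In the deeper sample the rule over the median of the other clusters named 209 cells (6.28%) epithelial-like from Krt8, Krt18 and Krt19, led by Ly6c1 and Ly6a, and the main rule did not. Both rules left its 917 cells with Krt8 and Krt18 unnamed.

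Mean correlation between replicates was 0.971 in iPax3, 0.874 in iPax7, 0.783 in Emb, 0.879 in Fet and 0.798 in Neo, and it was 0.918 between iPax3 and iPax7 libraries. The library labelled iPax7 replicate 1 correlated at 0.827 with each of the other two iPax7 libraries, which correlated at 0.967 with each other. It correlated at 0.849, 0.872 and 0.852 with iPax3 replicates 1 to 3. The first 3 principal components held 29.2, 21.4 and 9.93% of the variance. Emb replicate 1 lay apart from its group on the first (5.44, against 182 and 175), and Fet replicate 1 on the same axis (105.7, against -1.92 and 8.47).

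Ddx3y ranged from 0.743 to 127 CPM in PSC-derived libraries, where Xist was at most 23.9 CPM.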
